A study of Danio rerio with 10 samples.

How the data were processed

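Testes of adult male zebrafish (Danio rerio, AB strain) were profiled on an Affymetrix whole-transcript array, 1 array per sample. The fish had been exposed as juveniles to waterborne TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a dioxin that activates the aryl hydrocarbon receptor, AHR) at 50 pg/ml, or to the solvent DMSO alone. Per the labels' protocols, each exposure lasted 1 h and was given at 3 and again at 7 weeks after fertilization, the period of sexual differentiation and gonad maturation, and testes were taken at 1 year of age. Each group held 5 males, which the labels number as biological replicates. Total RNA was extracted with a column kit for lipid-rich tissue and labelled with biotin, per the labels' protocols.

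The deposited values were read as log2 expression values, 1 column per array, processed by the authors. The log2 scale was taken from their range of 1.25 to 14.6 and from the array medians of 6.71 to 6.87, since the base of the logarithm, the background correction and the normalization are not given in the sources used here. All columns were assigned to a sample by its label, and 0 were left unassigned. For arrays, the number of arrays limits the precision. With 5 against 5 arrays the median standard error of a log2 fold change was 0.18.

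The value table held 75212 probes. A table of the platform's annotation listed 20806 probes with 1 gene symbol, 855 with several and none for 53551. Of the probes with 1 symbol, 20323 matched a current entry by Entrez identifier, and 1 symbol was updated. Probes with several symbols named no gene, so that cyp1a, cyp1c1, ar and vtg1, which had been chosen for display, were not analysed here. For each gene the probe with the highest mean over all 10 arrays was used, which left 19260 genes. Of 1365 genes with more than 1 probe, 820 had all their probes on one side of 0, and the others disagreed in direction. Coordinates were not used here because no genome was given.

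The groups were compared with limma 3.58.1 in R 4.3.3, as a linear model on group with empirical Bayes variances, and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p under 0.05. A second count used an unadjusted p under 0.05 with at least a 1.5-fold difference. Differences are TCDD minus DMSO throughout, with a 95% confidence interval from the same model. Of the 30 gene lists fixed before the data were examined, 29 had at least 5 measured members and were tested with camera at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The list of mitochondrially encoded genes had no measured member under the naming pattern used and was not analysed here. Each list was also tested with camera's estimated correlation, with fry, and with an exact two-sided permutation test of the list mean per array over all 252 arrangements, whose smallest possible p is 0.00794. The lists covered testis cell types, hormone and metabolic pathways, stress responses and markers of tissues that border the testis.

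The genes named in the text followed a rule fixed with the lists. In each direction, genes past the adjusted threshold were to be named first. Where fewer than 5 passed, 10 were taken by smallest unadjusted p among genes with at least a 1.5-fold difference, without provisional clone names. Up to 4 members with the smallest p were taken per list, of which the text names those of lists that passed and, for the others, at least those with an interval off 0, and a fixed set of dioxin-response, steroid and germ-cell genes was always given.

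The model and the list test were tested on simulated data made for the comparison of TCDD with DMSO, with 5 arrays per group, 19260 genes and 200 changed genes in each of 10 simulations. At the adjusted threshold 60% of 2-fold and 91.6% of 4-fold changes were recovered, and 5.66% of calls were false. A list of 30 genes raised by 0.3 on the log2 scale had an unadjusted camera p under 0.05 in all 10 simulations, and an unchanged list in 0. The simulated genes varied independently, while members of the real lists varied together, with an estimated correlation of up to 0.88 for meiosis. The simulation therefore gives no rate of false calls for the real lists. It held no outlying array either, so its rates for genes may not hold for the real arrays.

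The labels give both groups the same replicate numbers. Nothing in them says that a number marks a shared litter or day, and the arrays were treated as unpaired. Alternatives fixed before the data were examined were the replicate number as a block, a variance trend with robust estimation, array weights, quantile normalization, median centring, a filter on dim probes, the mean of all probes of a gene, every probe, other thresholds, a plain t-test, other list tests, and leaving out each array. Alternatives that left out several arrays, added intestine and liver scores as covariates or permuted list means were chosen after seeing the data. The medians of all lists were also compared with those of 10000 random lists, whose genes lay within 100 ranks of the members by mean level, and except for muscle genes this was added after the results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.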

Results

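Gene expression was measured in the testes of 10 adult male zebrafish, 5 of which had been exposed to TCDD at 3 and 7 weeks of age and 5 to DMSO. The comparison asks whether a brief early exposure to dioxin is followed by a different testis transcriptome in adulthood. Array medians lay between 6.71 and 6.87 on the log2 scale, and pairwise correlations between arrays lay between 0.90 and 0.98. The DMSO 1 array stood apart, with a mean correlation of 0.918 to the others, and the first principal component, which held 56.0% of the variance, ranged from -33.6 in TCDD 1 to 47.5 in TCDD 2 and 109.3 in DMSO 1.

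The genes with the smallest p among those higher in TCDD testes included a voltage-gated potassium channel gene, 2 genes of steroid synthesis and its control, and a salt-inducible kinase gene, while the lower ones included lysozyme, lens and troponin genes. None of them passed the adjusted threshold. kcnh1a (probe 13045980), a potassium channel gene, averaged 9.34 ± 0.48 in TCDD and 8.13 ± 0.17 in DMSO (SD, n = 5 each), a difference of 1.21 (95% CI 0.74 to 1.69, limma adjusted p = 0.996), and its groups did not overlap. nr5a1b, which encodes a nuclear receptor of the steroidogenic factor 1 family, averaged 10.47 ± 0.29 against 9.49 ± 0.49, and sik1, a kinase gene induced by cAMP signalling, 9.45 ± 0.51 against 8.54 ± 0.30. cyp17a2, a steroid hydroxylase gene, differed by 0.71 (95% CI 0.25 to 1.18). The remaining genes of this kind were c3a.1 of the complement system at 1.58, meltf at 0.75, kcnh7 at 0.74, ndrg2 at 0.65, gadd45ga at 0.62 and slc25a38a at 0.59. On the lower side, lyz (probe 13151061), the lysozyme gene of granulocytes and macrophages, averaged 6.96 ± 0.19 against 8.01 ± 0.37, a difference of -1.05 (95% CI -1.45 to -0.65, limma adjusted p = 0.996), with no overlap between groups and the same sign for both of its probes. The others were npdc1a at -0.80, the troponin genes tnnt2b at -0.78 and tnni2a.3 at -0.68, the lens genes crygm2b at -0.75, crygm2d6 at -0.72 and lim2.1 at -0.71, olfcx1 at -0.61, ctsll at -0.60 and eya1 at -0.59. crygm2d6 and lim2.1 were dim, at the 9.2 and 10.3 percentile of all probes. crygm2b, ctsll, olfcx1, tnnt2b and tnni2a.3 also lay below the median probe, at percentiles of 35 to 47.

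Of 19260 genes, 0 passed a limma adjusted p of 0.05, where the smallest was 0.996. At an unadjusted p under 0.05 there were 478 genes (2.48%), fewer than the 963 that chance gives, with 154 higher and 324 lower in TCDD, and a plain test with equal variances gave 574 at that level and 0 after adjustment. With at least a 1.5-fold difference there were 114 genes, 63 higher and 51 lower, a split that became 66 and 29 after quantile normalization and 81 and 34 after median centring. Groups did not overlap for 0.493% of genes, against 0.794% by chance. Without DMSO 1 the count of 114 became 361, and without TCDD 2, DMSO 2 or DMSO 3 it became 195, 64 or 179. The share of genes at an unadjusted p under 0.05 was 6.65% without DMSO 1 and 10.7% with intestine and liver scores as covariates. Both are above the share that chance gives (smallest limma adjusted p of 0.393 and 0.108). Without TCDD 2, 1 gene passed, kcnh1a, at a difference of 1.41 (limma adjusted p = 0.0361).

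**Figure D1:**
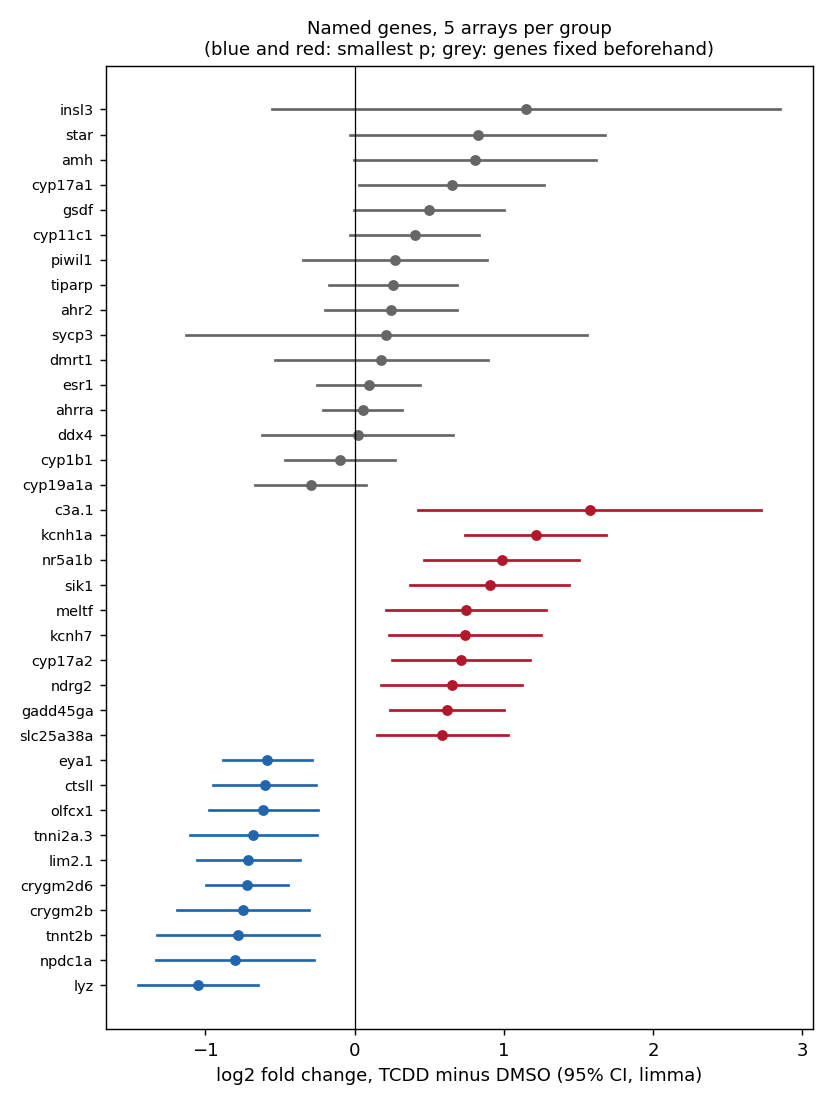
Log2 fold change of TCDD over DMSO on the horizontal axis for the genes of the naming rule (5 arrays per group), where points are estimates and lines 95% confidence intervals from limma. The red and blue genes were taken for their small p and range from 1.58 (c3a.1) to -1.05 (lyz), and the grey genes were fixed beforehand.

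Of 29 gene lists tested, 10 passed camera, 9 up and 1 down in TCDD, and 0 did with an estimated correlation. The count was 16 without TCDD 1 and 20 without DMSO 1.

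Genes of steroid synthesis and Leydig cells, the androgen-producing cells of the testis, lay higher in TCDD, with 21 of 27 measured members above 0 and a median difference of 0.26. Bright genes tended to be higher in TCDD, but random lists of genes at the same levels had a median of 0.04, and 0% of 10000 had one as high. camera called the list up (adjusted p = 2.25e-05), and the call was lost with an estimated correlation (adjusted p = 0.129). The list mean was 8.71 ± 0.10 in TCDD and 8.40 ± 0.18 in DMSO (SD, n = 5 each, exact permutation p = 0.0159, adjusted over the lists 0.153), and it lay above the DMSO mean in 5 of 5 TCDD arrays. The groups overlapped, with DMSO 3 at 8.62 above TCDD 2 at 8.55. Besides nr5a1b and cyp17a2, the members with the smallest p were cyp17a1, the 17-hydroxylase and lyase of androgen synthesis, at 0.65 (95% CI 0.03 to 1.27), and star, which carries cholesterol into mitochondria, at 0.83 (95% CI -0.03 to 1.68). nr5a1b was the 1 gene that passed when adjusted over the list alone (limma adjusted p = 0.0417), against 0 over all genes tested. cyp11c1 differed by 0.40 (95% CI -0.03 to 0.84) and insl3, a Leydig cell hormone, by 1.15 (95% CI -0.56 to 2.85). In DMSO 1 insl3 was at 7.09, against 11.13 or more in every other array. Without DMSO 1 the list median was 0.25, with star at 0.43, cyp17a1 at 0.40, insl3 at 0.28 and cyp11c1 at 0.21.

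Genes of Sertoli cells, which nurse the germ cells, and of testis differentiation lay higher as well, in 17 of 22 members, with a median of 0.27. camera gave an adjusted p of 2.06e-05, and 0.492 with an estimated correlation, and 0 members passed when adjusted over the list alone. gata4 differed by 0.59 (95% CI 0.12 to 1.05), sox9a by 0.85 (95% CI 0.08 to 1.62), amh, the anti-Müllerian hormone gene, by 0.81 (95% CI -0.00457 to 1.62) and gsdf by 0.50 (95% CI -0.00697 to 1.00), while dmrt1 differed by 0.18 (95% CI -0.53 to 0.89). The list mean was 9.26 ± 0.33 in TCDD and 8.94 ± 0.26 in DMSO (SD, n = 5 each, exact permutation p = 0.119, adjusted 0.690). It lay above the DMSO mean in 4 of 5 TCDD arrays. The mean was 8.52 in DMSO 1 and 8.78 in TCDD 2, both arrays with many intestine transcripts. Without TCDD 2 the median was 0.46, and without TCDD 4 it was 0.14. Without DMSO 1 amh differed by 0.49, gsdf by 0.33 and dmrt1 by -0.12. Random lists at the same levels had a median of 0.06.

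Immediate early genes, which respond within minutes to stimulation of a cell, showed the clearest separation of groups among the lists. Of 45 measured members 36 were higher in TCDD, with a median of 0.22 (0.01 in random lists at the same levels), and every TCDD array (8.02 to 8.23) lay above every DMSO array (7.70 to 8.01). The list mean was 8.11 ± 0.10 against 7.86 ± 0.11 (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible, adjusted 0.153). camera called the list up (adjusted p = 9.57e-09), and the adjusted p was 0.0748 with an estimated correlation. gadd45ba differed by 0.87 (95% CI 0.13 to 1.62), the AP-1 genes fosl2 by 0.45 (95% CI 0.10 to 0.79) and jund by 0.29 (95% CI 0.05 to 0.53), and nr4a1 by 0.41 (95% CI 0.06 to 0.77). 0 members passed when adjusted over the list alone.

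**Figure D2:**
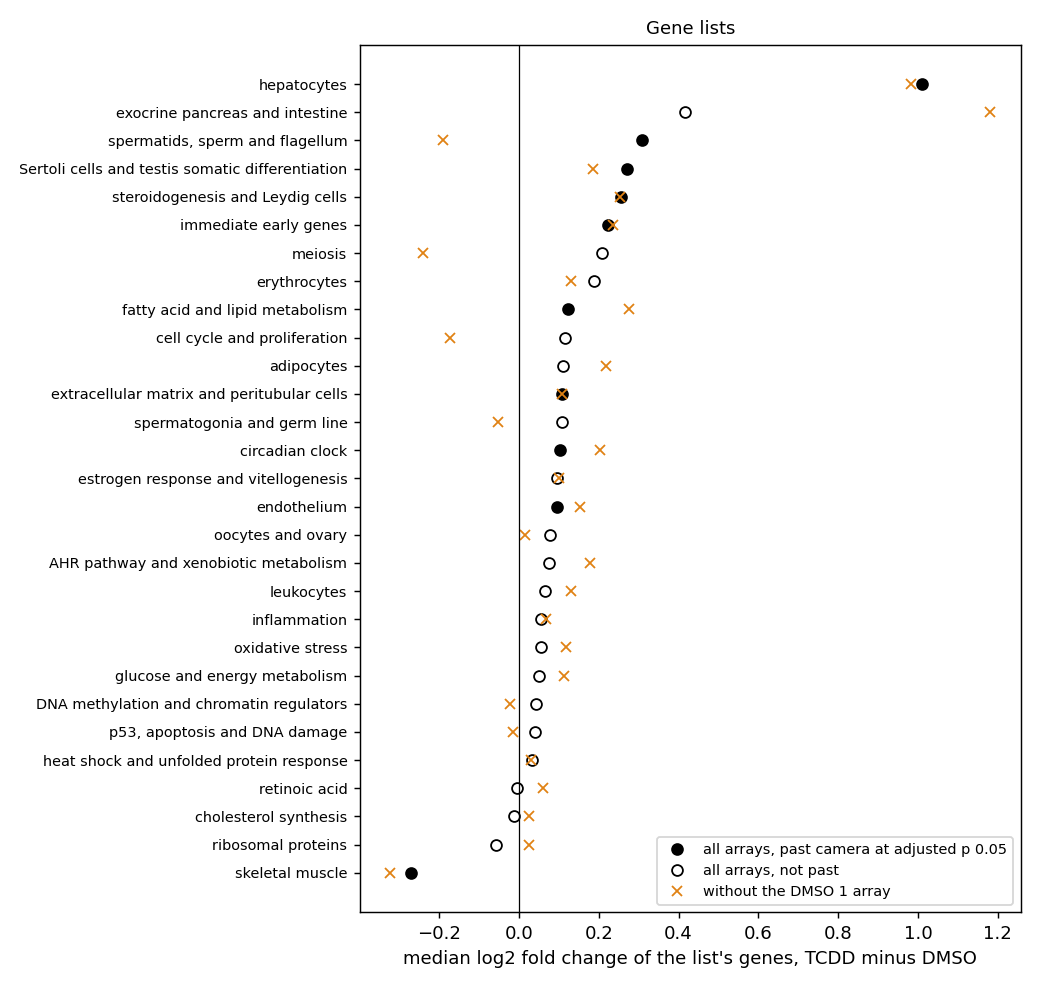
Median log2 fold change of each gene list on the horizontal axis, TCDD minus DMSO, for all 10 arrays (filled circles past camera at its preset correlation, open circles not) and without DMSO 1 (crosses). The hepatocyte list lies at 1.01, and the sperm, meiosis and cell cycle lists move from above 0 to below 0 without DMSO 1.

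Transcripts of germ cells did not show a direction that held across arrays. The list of spermatids, sperm and flagellum had 59 of 66 members above 0, a median of 0.31 and a camera adjusted p of 0.0025, which became 0.820 with an estimated correlation. Without DMSO 1 its median was -0.19 and camera called it down (adjusted p = 1.52e-07, and 0.508 with an estimated correlation). The list mean in DMSO 1 was 7.38, against 9.56 to 9.98 in the other DMSO arrays and 9.32 to 9.91 in TCDD. Without DMSO 5 the median was 0.47. Members with the smallest p were tppp2 at -0.41 (95% CI -0.80 to -0.02), ldhbb at 0.30, rfx2 at 0.31 and gapdhs at 0.23, and without DMSO 1 these were -0.32, 0.18, 0.06 and 0.09. Without TCDD 5 ldhbb was 0.15, and without DMSO 3 gapdhs was 0.37. Meiosis genes, with a median of 0.21 and an adjusted p of 0.0684, and cell cycle genes, with 0.12 and 0.0964, moved to -0.24 and -0.17 without DMSO 1, where camera called both down (adjusted p of 0.508 and 0.517 with an estimated correlation). It called both up when TCDD 2, TCDD 4, DMSO 2, DMSO 3, DMSO 4 or DMSO 5 was left out, with medians of 0.23 to 0.41 for meiosis and 0.11 to 0.23 for the cell cycle (adjusted p of 0.815 to 0.933 with an estimated correlation). With intestine and liver scores as covariates the meiosis, sperm and cell cycle medians were 0.64, 0.78 and 0.39 (adjusted p of 0.456 each with an estimated correlation). Among meiosis genes mcmdc2 differed by 0.41, trip13 by 0.47, the recombinase gene dmc1 by 0.71 and hsf5 by 0.55, against 0.05, 0.01, -0.05 and -0.20 without DMSO 1. Without DMSO 3 mcmdc2 was 0.62 and without DMSO 4 hsf5 was 0.83. The germ cell genes ddx4 (0.02, 95% CI -0.62 to 0.66), piwil1 (0.27, 95% CI -0.34 to 0.89) and sycp3 (0.21, 95% CI -1.13 to 1.56) had intervals that included 0 (-0.25, 0.01 and -0.43 without DMSO 1, and 0.19, 0.45 and 0.47 without DMSO 3). The spermatogonia list had a median of 0.11 (adjusted p = 0.450), which was -0.054 without DMSO 1, with camera's direction down, 0.058 without TCDD 5, 0.17 without DMSO 4 and 0.20 without DMSO 3. camera called it up with covariates (0.28, adjusted p = 0.548 with an estimated correlation) and without both DMSO 2 and DMSO 3 (0.26, adjusted p = 0.906 with an estimated correlation). Among its members gfra1b, a receptor gene of undifferentiated spermatogonia, differed by -0.28 (95% CI -0.48 to -0.07, limma adjusted p = 1.00), with no overlap between groups, id4 by -0.26, pou5f3 by 0.27 and nanos3 by 0.22, where pou5f3 and nanos3 were 0.11 and 0.14 without TCDD 4. The 2 probes of nanos3 disagreed in direction.

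Transcripts of tissues outside the testis differed widely between arrays. Genes of hepatocytes, which make the plasma proteins, were higher in TCDD in 32 of 33 members, with a median of 1.01 (camera adjusted p = 1.07e-15, and 0.430 with an estimated correlation). The list mean was 10.4 in TCDD 5, 7.67 to 8.58 in the other TCDD arrays and 7.07 to 7.84 in DMSO (exact permutation p = 0.0556), and without TCDD 5 the median was 0.42. Members with the smallest p were c3a.1, fga at 1.56 (95% CI 0.20 to 2.92), fgb at 1.48 (95% CI 0.09 to 2.87) and cp at 1.39 (95% CI 0.10 to 2.69), and without TCDD 5 the last 3 were 0.99, 0.82 and 0.81. Genes of exocrine pancreas and intestine did not pass, with a median of 0.42 (adjusted p = 0.111). camera called them up without DMSO 1 (median 1.18, adjusted p = 0.261 with an estimated correlation), TCDD 5 (0.86, 0.839) or TCDD 1 (0.58, 0.767), and without TCDD 2 the median was -0.024. Their mean was 11.4 in DMSO 1, 10.5 in TCDD 2, 9.04 in TCDD 4 and 8.90 in TCDD 3, and between 7.09 and 7.86 in the other 6 arrays. The peptide transporter gene slc15a1b of the intestine was at 10.1 in DMSO 1, 12.1 in TCDD 2 and 10.3 in TCDD 3, and at 7.06 or less elsewhere. The trypsin gene prss59.2 was high in every array, from 10.9 in DMSO 2 to 14.4 in DMSO 1.

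Skeletal muscle genes were lower in TCDD, in 34 of 40 members, with a median of -0.27. camera called the list down (adjusted p = 1.77e-12, and 0.129 with an estimated correlation), and 0 members passed when adjusted over the list alone. The list mean was 6.92 ± 0.05 in TCDD and 7.22 ± 0.30 in DMSO (SD, n = 5 each, exact permutation p = 0.0159, adjusted 0.153), with the highest values in DMSO 3 (7.63) and DMSO 2 (7.47), and without these arrays the median was -0.089. tnnt3b differed by -0.79 (95% CI -1.37 to -0.22), mybpc2b by -0.50 (95% CI -0.86 to -0.13), pvalb1 by -0.47 (95% CI -0.79 to -0.14) and pvalb2 by -0.44 (95% CI -0.78 to -0.10).

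**Figure D3:**
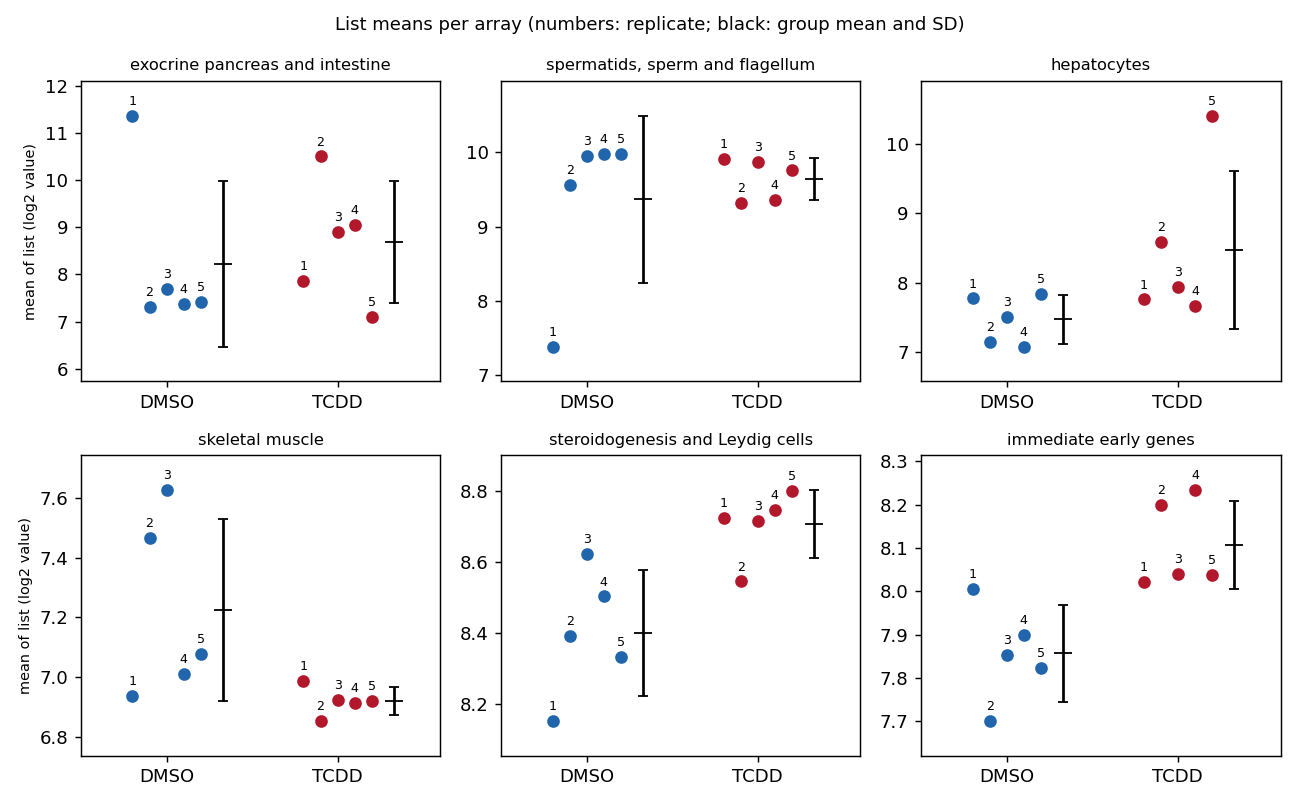
Mean log2 value of 6 gene lists on the vertical axis for each of 5 DMSO (blue) and 5 TCDD (red) arrays, numbered by replicate, with the group mean and SD in black. DMSO 1 is highest for intestine and pancreas (11.4) and lowest for sperm (7.38), TCDD 5 is highest for hepatocytes (10.4), and the 5 TCDD arrays lie above all DMSO arrays for immediate early genes.

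The 4 dioxin-response genes that were fixed beforehand and measured all had intervals that included 0 over the 10 arrays. The AHR-induced gene cyp1b1 differed by -0.10 (95% CI -0.47 to 0.27), the receptor gene ahr2 by 0.24 (95% CI -0.20 to 0.69), its repressor ahrra by 0.05 (95% CI -0.21 to 0.32) and tiparp by 0.26 (95% CI -0.17 to 0.69). When single arrays were left out these ranged from -0.19 to 0.00015, 0.14 to 0.44, 0.014 to 0.12 and 0.18 to 0.40. cyp1b1 and ahrra lay below the median probe, at the 41.8 and 42.2 percentile of all probes, so background could hide a difference in them. ahr2 and tiparp were brighter, at 88.1 and 93.8. The AHR and xenobiotic list had 15 of 23 members above 0, a median of 0.07 and a camera adjusted p of 0.151. Its member with the smallest p was cyp1d1 at 0.41 (95% CI -0.03 to 0.84), and gsta.1 was at -0.34 (-0.084 without DMSO 1). Without DMSO 1, whose list mean of 8.24 was the highest, the median was 0.18 and camera called it up (adjusted p = 0.00159, and 0.125 with an estimated correlation), with ahr2 at 0.44 ± 0.12 (SE, limma adjusted p = 0.717). It was also called up without TCDD 1 (median 0.069, adjusted p = 0.624 with an estimated correlation). The estrogen receptor gene esr1 differed by 0.10 (95% CI -0.25 to 0.44) and the aromatase gene cyp19a1a by -0.29 (95% CI -0.67 to 0.08). The estrogen response list (median 0.10, adjusted p = 0.608) and the oocyte list (median 0.08, adjusted p = 0.201) did not pass, though camera called oocyte genes up without TCDD 1 (0.14) or TCDD 2 (0.21), with adjusted p of 0.749 and 0.873 for an estimated correlation. For the estrogen response list camera's direction turned from up to down without TCDD 4 or DMSO 3. The oocyte list mean was 7.68 in TCDD 3 and 7.75 in TCDD 4, against 6.98 to 7.40 in the other 8 arrays, and without TCDD 4 the median was -0.0032 and without TCDD 3 0.026. The egg coat gene zp2.1 was at 8.21 and 8.52 in these arrays and at 6.55 or less elsewhere, zp3b at 8.25 and 8.095 against 7.44 or less, and btg4 at 7.68 and 8.14 against 7.16 or less.

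Another 4 lists passed camera with small medians, and each had an adjusted p of 0.820 with an estimated correlation. Fatty acid and lipid genes had a median of 0.12 (adjusted p = 0.0053), with fads2, a fatty acid desaturase gene, at 1.02 (95% CI 0.03 to 2.01), cpt1b at 0.91, fabp7b at -0.36 and slc27a2a at 0.97. fads2 was highest in TCDD 5 (11.6) and TCDD 3 (10.8). Extracellular matrix and peritubular genes had a median of 0.11 (adjusted p = 0.00775), with ccn2a at 1.13 (95% CI 0.09 to 2.16), ccn2b at 0.32, bgnb at 0.50 and fn1b at 0.58. Without TCDD 5 fads2 differed by 0.63, cpt1b by 0.58 and fn1b by 0.35. Circadian clock genes had a median of 0.10 (adjusted p = 0.0302), with nfil3-5 at 0.30, nfil3-6 at 0.79, nr1d4b at 0.38 and rorcb at 0.33, where nfil3-6 was 0.43 and nr1d4b 0.19 without TCDD 2. Endothelial genes had a median of 0.09 (adjusted p = 0.0302), with plvapa at 0.75, plvapb at 0.33, s1pr1 at 0.34 and lyve1a at -0.19. Random lists at the same levels had medians of 0.047, 0.027, 0.055 and 0.020 for the 4 lists in turn. A median as high came from 0.08%, 0%, 3.98% and 0.42% of them. Each of the 4 calls was lost without DMSO 3 (medians 0.10, 0.12, 0.12 and 0.11) and without DMSO 2 (0.063, 0.028, 0.069 and 0.069). The circadian call was also lost without TCDD 2 (0.0065), DMSO 4 (0.072) or DMSO 5 (0.036), with medians of 0.062 without TCDD 1 and 0.16 without TCDD 4, the endothelial one without TCDD 2 (0.086), TCDD 4 (0.067) or DMSO 4 (0.12), and the matrix one without TCDD 4 (0.012), while without DMSO 1 the fatty acid, circadian and endothelial medians were 0.28, 0.20 and 0.15, with slc27a2a at 1.51, nfil3-6 at 1.17 and plvapa at 1.15.

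The leukocyte list did not pass (adjusted p = 0.614), with a median of 0.06 and a mean of 0.01 above 0 while camera's direction was down. Within it lyz passed when adjusted over the list alone (limma adjusted p = 0.00641), and the B-cell receptor genes cd79a and cd79b differed by -0.30 and -0.26 (-0.17 for cd79b without DMSO 2) and cd247l by -0.29. Inflammation (median 0.05, adjusted p = 0.117), erythrocyte (0.19, 0.138), adipocyte (0.11, 0.608), glucose and energy (0.05, 0.0684), oxidative stress (0.05, 0.303) and p53 and apoptosis genes (0.04, 0.608) did not pass. Nor did chromatin and DNA methylation (median 0.04, adjusted p = 0.138), heat shock (0.03, 0.838), cholesterol synthesis (-0.01, 0.350) and ribosomal protein genes (-0.06, 0.0555). Retinoic acid genes had a median of -0.01 and a mean of 0.04, with an adjusted p of 0.838. Single members of these lists had intervals off 0, namely irf7 of inflammation at 0.43 (95% CI 0.01 to 0.85), the ribosomal gene rpl38 at -0.40 (95% CI -0.69 to -0.11), the retinol dehydrogenase gene rdh5 at -0.34 (95% CI -0.63 to -0.05), the heat shock gene serpinh1b at -0.38 (95% CI -0.76 to -0.00349) and pmaip1 of the p53 list at -0.38 (95% CI -0.73 to -0.02, and -0.24 without DMSO 1). The p53 list also holds gadd45ba, which went the other way, at 0.87 (95% CI 0.13 to 1.62).

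The calls of several of these lists depended on single arrays, and 0 passed with an estimated correlation in any of these fits. Without DMSO 1 camera called glucose (median 0.11), oxidative stress (0.12), inflammation (0.066), adipocyte (0.22), leukocyte (0.13) and retinoic acid genes (0.060) up, with adjusted p of 0.249, 0.253, 0.261, 0.261, 0.508 and 0.249 for an estimated correlation. For leukocytes its direction was down over all arrays, with covariates and without DMSO 2 and DMSO 3. Without TCDD 1 camera called glucose (0.081), oxidative stress (0.060) and inflammation genes (0.072) up, and without TCDD 3 inflammation genes (0.070), with 0.657, 0.749, 0.624 and 0.920. Erythrocyte genes were called up without TCDD 4 (0.24), TCDD 5 (0.26), DMSO 2 (0.22) or DMSO 5 (0.27), with 0.815 to 0.882. Without TCDD 2 camera's direction for erythrocyte genes was down, and they were not called. Ribosomal protein genes were called down without TCDD 2 (-0.075), DMSO 2 (-0.070), DMSO 3 (-0.039), DMSO 4 (-0.066) or DMSO 5 (-0.063), with 0.815 to 0.933. Without DMSO 1 camera's direction for them was up, and they were not called.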

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

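The tests of the steroidogenesis list, of a shared rise of other cell types, of a shared fall of testis cell types and of the single lists over splits of the arrays were chosen after the results were seen. So was the requirement that a list's array means differ at a p under 0.05, by exact permutation or, with covariates, by a linear model.

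The DMSO 1 array lay far from the other DMSO arrays for 21 of the 26 values found this way, among 234 tested, where chance gives about 1 in 20, or 12. Its gap to the nearest array, as a share of the group's range, was 0.905 for the mean of intestine and pancreas genes, 0.839 for spermatids and sperm, 0.775 for meiosis, 0.748 for the cell cycle, 0.823 for AHR and xenobiotic genes, 0.811 for oocytes, 0.832 for estrogen response, 0.76 for leukocytes, 0.717 for fatty acids, 0.719 for retinoic acid and 0.735 for oxidative stress. For single genes the share was 0.868 for insl3, 0.836 for nfil3-6, 0.823 for plvapa, 0.818 for hsf5, 0.811 for cyp11c1, 0.799 for nr4a1, 0.769 for slc27a2a, 0.766 for star, 0.726 for dmc1 and 0.713 for trip13. TCDD 2 was low for insl3 (0.852) and for the cholesterol synthesis list (0.811). DMSO 2 was low for the extracellular matrix list (0.74), and DMSO 5 was high for fgb (0.772) and low for ndrg2 (0.711).

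In DMSO 1 intestine and pancreas genes were high, by a median of 3.94 against the other DMSO arrays, and sperm genes low, by -2.84. A lower share of germ cells would raise other cell types alike, which the tables argue against, because the intestine and pancreas list exceeded the next of the endothelial, leukocyte, erythrocyte, muscle and hepatocyte lists by 3.53, more than its own spread of 1.04. A candidate explanation is intestine tissue in the DMSO 1 sample, since a second set of intestine genes, written before its values were seen, was higher in 21 of 21 measured members, with a median of 2.95 (7.72-fold), although 13 of the 21 lay above the median probe in the other DMSO arrays. Displacement by that tissue or a small testis sample would lower all testis cell types alike. The Leydig, Sertoli and spermatogonia lists shifted by -0.13, -0.38 and -0.85, the lowest of them 1.99 (1.986) above the sperm list, more than the largest spread of 0.99. The list medians do not decide this, since list members may also be expressed in the other tissue. In DMSO 1 star (8.80, against 10.48 or more in the other DMSO arrays), amh (9.67, against 10.88) and ddx4 (10.58, against 11.7) were low as well, while gata4, sox9a and gfra1b were not. What lowered sperm genes and insl3 stays open, and no biological explanation was tested, since the array is a single control.

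Skeletal muscle genes were lower in TCDD, and 1 of 100 splits of the arrays, the real one, gave as small a camera p (-log10 p of 12.9, against 10.6 in the highest other). The list was singled out of 29, and its exact permutation p adjusted over all of them was 0.153. That test could hardly pass over 29 lists, since its smallest possible p is 0.00794. A lower background of dim probes is argued against as the whole cause, since the list's median lay at percentile 0 of 10000 random lists matched on level, although 64.2% of the 4815 dimmest genes were lower in TCDD and random lists leave out the correlation of muscle genes. Muscle RNA in DMSO 2 and DMSO 3 stays open. Without both arrays the median was -0.089, and camera still called the list (adjusted p = 0.187 with an estimated correlation). A bound set beforehand had taken such a call to exclude this cause. The exact permutation test of the array means, required later, gave p = 0.0714 over 56 arrangements. That cause and an effect of TCDD cannot be told apart for this list, since 3 DMSO arrays are too few.

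Steroidogenesis and Leydig genes were higher in TCDD, and 1 of 100 splits, the real one, gave as small a camera p (-log10 p of 5.41, against 3.94 in the highest other). DMSO 1 as the whole cause is argued against by a median of 0.25 (0.254) without it (exact permutation p = 0.0238). With intestine and liver scores as covariates the median was 0.195, and the list mean differed by 0.36 ± 0.08 (SE). That fit does not decide dilution by both tissues, which stays open. It kept DMSO 1, whose intestine and pancreas mean was 11.4, against 7.69 or less in the other DMSO arrays. With covariates insl3 differed by 1.97, against 0.28 without DMSO 1. A shift of all genes at the level of the list is argued against by 0% of 10000 random lists with as high a median, although random lists leave out the correlation of its genes. For immediate early genes, too, 1 of 100 splits gave as small a camera p, the real one (-log10 p of 9.0, against 7.65). These lists were singled out of 29, and over all of them the exact permutation test gave an adjusted p of 0.153. That value was nearly fixed in advance, since immediate early genes had the smallest possible p of 0.00794 and still had 0.153. It therefore neither excludes chance nor argues for it. A difference in the share of Leydig cells, in the handling of the fish, and an effect of TCDD stay open as untested explanations.

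The count of 0 genes at the adjusted threshold cannot be tested by splits, since all 100 reach 0 whatever the data, with 2 in the highest other split. Chance could not be excluded for the other counts. With a 1.5-fold difference 52 of 100 splits gave at least 114 genes, with 1685 in the highest other, which set DMSO 3, DMSO 4, DMSO 5, TCDD 1 and TCDD 5 against the rest. Of the 46 splits with DMSO 1 and TCDD 2 on one side 42 reached the real count, against 10 of the 54 that parted them, which points to a structure of the arrays apart from the exposure. For gene lists 75 of 100 splits gave at least 10, with 22 in the highest other.

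Chance was not excluded for the muscle, steroidogenesis and immediate early lists, which were singled out of 29. Nor could it be excluded for the other 7 lists that camera called. As small a camera p came from 5 of 100 splits for Sertoli genes (-log10 p of 5.55, against 6.75 in the highest other), 7 for hepatocytes (16.4, against 23.4), 89 for sperm (3.29, against 18.3) and 41 for fatty acids (2.89, against 12.1). It came from 39 for the circadian clock (1.98, against 8.98), 36 for extracellular matrix (2.67, against 9.07) and 34 for endothelium (2.01, against 6.03).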

How the results depend on the processing

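The fits that left out several arrays, used scores as covariates or permuted list means were chosen after seeing the data, and except where stated the cause of a change was not tested. The count of genes past the limma adjusted threshold stayed at 0 except at 1 without DMSO 1 and TCDD 2, and ranged from 0 to 1 when single arrays were left out. The 114 genes at an unadjusted p with a 1.5-fold difference became 351 with array weights, 61 among genes above the median level (fewer genes tested), 1555 over every probe (more tested), 73 with a plain test, 464 at 1.2-fold and 18 at 2-fold (by construction), 364 without DMSO 1 and TCDD 2, 423 without DMSO 1, TCDD 2 and TCDD 5, and 932 with intestine and liver scores as covariates, and ranged from 64 to 361 without single arrays. The 10 gene lists became 18 with array weights and without DMSO 1 and TCDD 2, also 18 without DMSO 1, TCDD 2 and TCDD 5, and 0 with an estimated correlation, fry or exact permutation, and ranged from 9 to 20 without single arrays. The 0 for exact permutation was nearly fixed in advance, since the complete separation of immediate early genes still gave an adjusted p of 0.153.

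Deviations from the group mean gave no sign that the shared replicate numbers pair the arrays. Those of same-numbered arrays correlated at -0.58, -0.21, -0.028, -0.037 and 0.29, and those of each TCDD array correlated better with a DMSO array of another number. This cannot exclude a pairing, since each number was set against the best of several others, and DMSO 1 lay far from its group. With a replicate block the counts were 0 genes, 143 at the unadjusted level and 11 lists.

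Directions of lists called in either fit turned as follows. Meiosis, sperm and cell cycle medians were -0.14, -0.097 and -0.077 with array weights, -0.17, -0.12 and -0.059 without DMSO 1 and TCDD 2, and -0.16, -0.14 and -0.050 without TCDD 5 as well, but 0.51, 0.59 and 0.29 without DMSO 2 and DMSO 3 and 0.64, 0.78 and 0.39 with covariates, each called up (adjusted p of 0.906 and 0.456 with an estimated correlation). With single arrays left out they ranged from -0.24 to 0.41, -0.19 to 0.47 and -0.17 to 0.23, with the lowest without DMSO 1, where camera turned up for leukocytes (range of medians -0.016 to 0.13) and retinoic acid (-0.029 to 0.060), with adjusted p of 0.508 and 0.249 for an estimated correlation. With covariates camera turned down for hepatocytes (0.016, whose score is the covariate), fatty acids (0.027), circadian (0.027) and oxidative stress genes (-0.096, called, with an adjusted p of 0.457 for an estimated correlation), and without DMSO 2 and DMSO 3 for fatty acids (0.019) and endothelium (0.0037). Directions also turned for lists called in neither fit, 7 with covariates, 7 without DMSO 2 and DMSO 3, 6 without DMSO 1, TCDD 2 and TCDD 5, 5 without DMSO 1 and TCDD 2, 5 with array weights, 0 to 4 without single arrays and 0 to 3 in the rest. AHR genes (medians 0.0054 and 0.020) and intestine and pancreas (-0.073 and -0.023) turned in the first 2. Of the genes given with a difference, 45 had an interval off 0, and 0 of them changed sign in the 21 alternatives fitted for single genes. This was nearly fixed in advance. Most of these genes were chosen for small p in the same arrays, and alternatives such as the replicate block or the variance trend leave the estimate unchanged. Signal over background was not tested, as it needs scanner values.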

Other observations

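Crystallins, the structural proteins of the lens, were lower in TCDD in 30 of 41 measured genes, with a median of -0.13. Their mean was 5.90 ± 0.08 in TCDD and 6.04 ± 0.10 in DMSO (SD, n = 5 each, exact permutation p = 0.0238), and 39 of them lay in the dimmer part of all genes. The family was chosen after crygm2d6 and crygm2b had been seen. A lower background of dim probes in the TCDD arrays could produce this, since random lists of genes at the same levels had a median of -0.06. The crystallin median lay at percentile 2.04 of 10000 such lists, below the bound of 2.5% set beforehand, which had taken such a value to exclude this cause. Without the 2 genes seen first, a condition that the bound did not hold, it lay at 3.61. That background stays open, since most of these genes were dim, and paralogs with shared sequence vary together while random genes do not.

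The intestine transcripts were not of one kind. slc15a1b, of the anterior intestine, was at 10.3 in TCDD 3 and 6.71 in TCDD 4. A hypothesis was that the samples hold different segments of the intestine. All 11 genes of an anterior set, written beforehand, were higher in TCDD 3, with a median difference of 1.25 and the largest for pla2g12b at 5.12. Of 7 posterior genes 5 were lower in TCDD 3, among them cubn at -1.90 and slc10a2 at -1.27, but their median of -0.23 did not reach the -0.5 set beforehand. The sets differed by 1.47, which may reflect different segments, and 7 posterior genes, of which 5 lay above the median probe in DMSO 2 to DMSO 5, are too few to decide. A different share of pancreas, which the list pools with intestine, was not tested. The trypsin gene prss59.2 was at 13.8 in TCDD 4 and 12.9 in TCDD 3.

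Level and direction went together over all genes. The median difference was -0.07 in the 4815 dimmest genes, where 64.2% were lower in TCDD, and 0.08 in the 4815 brightest, where 24.9% were lower.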
